A study of Mus musculus with 5 samples.

How the data were processed

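Small RNA was sequenced from 5 mouse testis cell libraries. Per the labels, the donors were C57BL/6 mice, RNA was isolated with Trizol, and libraries followed the Illumina small RNA protocols, including the v1.5 variant. Testis cells had been separated with magnetic beads carrying an antibody against Thy1.2, a surface protein used to enrich spermatogonial stem cells. There were 2 libraries of the retained Thy1+ fraction, 2 of the depleted Thy1- fraction, and 1 of a germ cell culture started from enriched cells and kept for about 10 passages. Groups and replicate numbers came from the sample titles. The cell type label of the Thy1- samples repeats the stem cell name, while their titles and source name call them enriched for somatic cells, and the titles were used. The labels do not state that replicates came from separate animals, so p-values measure the spread between these samples. With 1 culture library, that spread comes from the fresh libraries alone.

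The deposited files list, for each distinct sequence tag, its counts, which are raw read counts without normalization, together with each mature miRNA it was placed on, the position and up to 2 mismatches. Per the file names, tags were annotated to the mature mouse miRNAs of miRBase 12.0 and the stated upper tag length was 35 bases. The tags in the files span 15 to 25 bases. The submitters' processing notes name DESeq without a version or a role. The adapter removal, the aligner and the genome build are not given in the sources used here. Only reads placed on a miRNA are in the files, so the totals are miRNA reads and not whole sequencing depths.

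Each tag was assigned to the mature miRNA of its best placement, meaning the fewest mismatches. Tags tied between several names, at most 8, were split equally, and sums were rounded to whole counts. Names follow the files without the mouse prefix, and an asterisk marks the minor strand of a hairpin. This gave 593 miRNA names with a count in any library. Levels are given as counts per 1000000 (CPM) of a library's miRNA counts, as mean ± SD with n = 2 in the fresh groups and a single value in the culture. Because levels are shares, a few very abundant miRNAs can lower all others. Tags with mismatches were counted, so near-identical family members can exchange counts. Names whose tags were all tied carry equal values, namely miR-199a-3p with miR-199b, 3 products of miR-465, 4 of miR-466, miR-467a* with miR-467d*, and let-7a* with let-7c-2*. They are 1 measurement each but count as separate names.

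Differential abundance was computed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit, TMM scaling, filterByExpr, two-sided). Every adjusted p for a miRNA is from edgeR with the Benjamini-Hochberg correction over all miRNAs tested, with a threshold of 0.05. Thy1+ and Thy1- were compared with the 4 fresh libraries only. The culture was compared with each fresh fraction in a fit of all 5 libraries, in which the single culture library is assumed to vary like the fresh groups. Log2 fold changes are on the TMM scale with their standard error (SE). Scaling to total counts instead moved the median log2 fold change of all miRNAs by 0.58 for Thy1+ against Thy1-, by -1.64 for culture against Thy1+ and by -1.04 for culture against Thy1-. Changes are therefore relative to the bulk of miRNAs, and the split under total scaling is given for each comparison and for lists whose count it moved by more than 1.5 times.

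The comparisons, tests, miRNA lists and alternatives were chosen before the data were examined, except where said otherwise. There were 17 lists. They were a study list (miR-21, miR-34c, miR-182, miR-183, miR-146a), the miR-183 cluster, the miR-34 family, the miR-17 clusters, the pluripotency clusters (miR-290 to miR-295 and miR-302), let-7, the miR-221 pair, the X-linked testis cluster, gonadal miR-202, the Dlk1-Dio3 cluster and the Sfmbt2 cluster. Lists for other cell types were mesenchymal, striated muscle, endothelial, blood cells, the epithelial miR-200 family and other tissues. A list held every mature product of its hairpins, except let-7c-1*, let-7c-2* and miR-466b-3-3p, whose names carry a copy number and were not matched. Members past the test were counted with adjustment over all miRNAs and over the list alone. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. They were also tested with fry, a test of the list members alone. Each test was adjusted over the lists. The study list is known to have been picked by the study from these libraries. It shares miR-182 and miR-183 with the miR-183 cluster and miR-34c with the miR-34 family.

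Named miRNAs were taken by rule. They were the 5 with the highest mean CPM in each group, up to 10 per direction with the largest called change among those with at least 100 CPM in the higher group and no overlap between groups, the up to 4 most abundant members of each list, and the mature members of the study list. Where a list had few called members, the others called were named too, after their values were seen. Positions were found by searching 491 mature sequences from the exact tags in annotated hairpins of GRCm38 (GENCODE mouse release 21), and 487 were located. This annotation was not necessarily that of the authors.

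Depth ranged from 937002 to 5110007 counts per library. A miRNA with a count of 0 could hold up to 3 counts, which is 3.20 and 3.17 CPM in the Thy1+ libraries, 1.18 and 0.611 CPM in the Thy1- libraries and 0.587 CPM in the culture. Shares of 1 library carry 95% Clopper-Pearson intervals. Reads carry no molecular identifiers, so intervals and these limits cover counting error only. Fitted changes of miRNAs without a culture count are not bounds, and list medians are also given with those members set to 3 culture counts.

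The fit was tested on simulated data with 200 changed miRNAs per run in 5 runs. With 425 genes, as for Thy1+ against Thy1-, 14.3% of 2-fold, 69.6% of 4-fold and 97.9% of 8-fold changes were recovered and 1.78% of unchanged genes were called. With 470 genes, as for culture against Thy1+, recovery was 6.57%, 31.9% and 72.1% at the same folds, with 1.19% of unchanged genes called. With 470 genes, as for culture against Thy1-, it was 6.27%, 31.0% and 72.7%, with 0.519% called. The simulated culture was given the spread of the fresh groups and equal numbers of rises and falls. These rates therefore do not test whether the real culture varies like the fresh groups, nor the choice of scaling. A simulated set of 15 members shifted 4-fold was found by the preset camera test in 5 of 5 runs of each comparison and with an estimated correlation in 0 of 5, while the preset test called 1 of 80 random sets for Thy1+ against Thy1- and 0 of 80 for each culture comparison. The simulated members varied independently, so this does not cover lists whose members vary together. For Thy1+ against Thy1- the estimated correlation was 0.562 in the pluripotency clusters, 0.399 in the miR-183 cluster and 0.0101 in the X-linked cluster. For culture against Thy1+ it was 0.378 in the Dlk1-Dio3 cluster. Where it lies above the preset 0.01, the preset camera p can be too small.

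The alternatives were RLE, total and upper-quartile scaling, no filter, a filter at 100 CPM, DESeq2 1.42.0, limma-voom, only tags with a single name, tied tags counted in full, exact tags only, tags seen at least 2 times, tags of 20 to 24 bases, an adjusted p of 0.10, leaving out each fresh library, other sets of libraries in the fit, and the replicate number as a block. A block with crossed numbers and taking names of equal counts once were added after the data were seen. Tag tables were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. No library was left out.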

Results

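The data were small RNA reads on mature miRNAs from 2 Thy1+ testis cell libraries, enriched for spermatogonial stem cells, 2 Thy1- libraries, enriched for somatic cells, and 1 library of cultured germ cells at about 10 passages. Spermatogonial stem cells are the self-renewing cells from which sperm production starts. The Thy1+ libraries held 937002 and 947687 counts, the Thy1- libraries 2548234 and 4909753, and the culture 5110007. Between 510 and 547 miRNAs had a count in each library.

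A few miRNAs made up much of each library. The 5 most abundant in the Thy1+ fraction were let-7c, miR-34c, let-7a, let-7f and miR-182, with let-7c at 87328 ± 7832 CPM (SD, n = 2). In the Thy1- fraction they were let-7c, let-7f, let-7a, let-7b and miR-99b. In the culture they were miR-34c at 195531 CPM, let-7f at 123547, miR-21 at 118930, let-7a and let-7c. The 10 most abundant held 45.6% (45.45% to 45.65%) and 37.9% (37.76% to 37.96%) of the Thy1+ counts, 58.4% (58.31% to 58.44%) and 60.3% (60.24% to 60.33%) of the Thy1- counts and 68.9% of the culture counts (68.88% to 68.96%), with 95% Clopper-Pearson intervals in brackets. The Thy1+ and Thy1- means of that share, 41.7% ± 5.44 and 59.3% ± 1.35 (SD, n = 2), gave a two-sided exact permutation p of 0.333, the smallest that 2 against 2 libraries allow, adjusted to 0.533 over 8 library measures. Across 470 miRNAs, replicate libraries had a Spearman rho of 0.960 for Thy1+ and 0.963 for Thy1-, against 0.799 to 0.898 for libraries of different groups (miRNAs are not independent replicates).

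**Figure D1:**
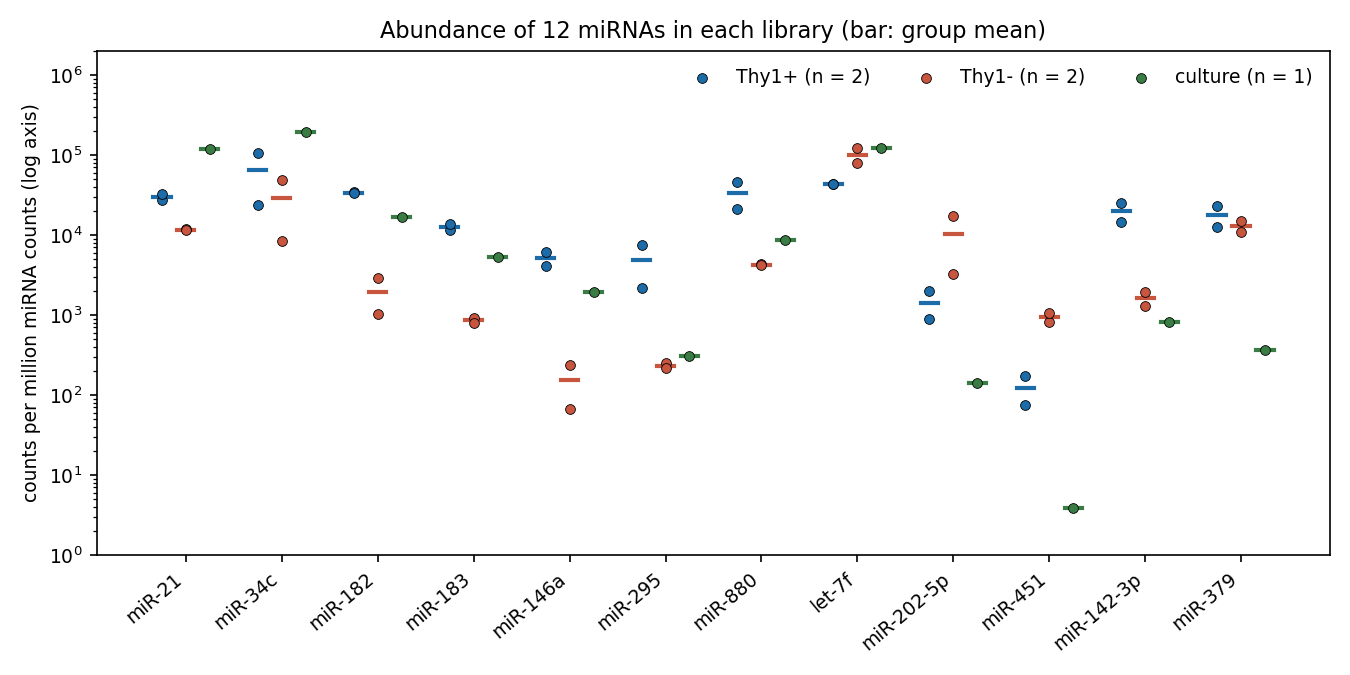
Abundance of 12 miRNAs in the 5 libraries, in counts per 1000000 miRNA counts (CPM) on a log axis. Each point is a library, coloured by group (Thy1+, n = 2; Thy1-, n = 2; culture, n = 1), and each bar is the group mean. miR-146a lies at 5132 CPM in Thy1+ and 153 CPM in Thy1-, and miR-379 at 363 CPM in the culture and 17665 CPM in Thy1+.

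The first comparison asked which miRNAs distinguish the stem cell enriched Thy1+ fraction from the Thy1- fraction of the same kind of testis. Of 425 miRNAs tested, 86 rose and 33 fell in Thy1+. The miRNAs that rose included all 4 products of the miR-183 cluster, which is known from sensory organs, 11 of 12 of the miR-290 to miR-295 cluster, which is known from embryonic stem cells, 15 of 27 of a testis cluster on the X chromosome and 6 of white blood cells. The miRNAs that fell included 10 of 15 products of let-7, a family known for promoting differentiation, both of the gonadal miR-202 and 3 of red blood cells. Among the largest rises was that of miR-146a, a regulator of innate immune signalling, from 153 ± 120.5 CPM in Thy1- to 5132 ± 1499 CPM in Thy1+ (SD, n = 2), which is 4.56 on the log2 scale (SE 0.67, edgeR adjusted p = 0.0116).

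Of 8 products of the study list, 4 rose, and 4 also did when adjusted over the list alone (camera adjusted p = 1.63e-03; adjusted p = 0.259 with an estimated correlation). The list was chosen by the study on these samples, so its direction is not independent evidence. miR-146a, miR-182, miR-183 and miR-183* rose. miR-182 stood at 33655 ± 789.9 CPM in Thy1+ and 1961 ± 1323 CPM in Thy1- (log2 3.61, SE 0.60), and miR-183 at 12729 ± 1494 and 857 ± 75.6 CPM (log2 3.33, SE 0.47). miR-21, a miRNA abundant in many proliferating cells, was at 30144 ± 3666 CPM in Thy1+ and 11617 ± 129.8 CPM in Thy1-. Its log2 fold change of 0.81 (SE 0.45) did not pass the test (adjusted p = 0.215). miR-34c, known from meiotic and later male germ cells, differed more between replicates than between fractions, with 105483 and 23388 CPM in Thy1+ and 48794 and 8498 CPM in Thy1- (log2 0.80, SE 0.93, adjusted p = 0.547). In GRCm38 the miR-21 hairpin lies on chromosome 11 at 86584067 to 86584158, in an exon of Vmp1, and that of miR-34c on chromosome 9 at 51103034 to 51103110, opposite an intron of Btg4. miR-182 (chromosome 6, 30165918 to 30165992), miR-183 (chromosome 6, 30169668 to 30169737) and miR-146a (chromosome 11, 43374397 to 43374461) overlapped no other annotated gene among those searched. Genes that the annotation types as miRNA or TEC were left out of this search.

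All 4 products of the miR-183 cluster rose, also when adjusted over the list alone (camera adjusted p = 7.55e-05; adjusted p = 0.263 with an estimated correlation), among them miR-96 at log2 3.54. Of 12 products of the pluripotency clusters, 11 rose, and 11 did when adjusted over the list alone (camera adjusted p = 2.11e-07; adjusted p = 0.323 with an estimated correlation). All 12 tested products were of miR-290 to miR-295 on chromosome 7 (3218626 to 3220841), since those of miR-302 had too few counts to be tested. miR-295 reached 4822 ± 3724 CPM in Thy1+ against 234 ± 20.8 in Thy1- (log2 3.74, SE 0.64), miR-292-5p rose by 3.97 and miR-291a-3p by 3.59. In the X-linked testis cluster (66776757 to 67988451), 15 of 27 products rose (13 of 25 with names of equal counts taken once) and 0 fell, or 21 and 1 when adjusted over the list alone (camera adjusted p = 1.94e-06; adjusted p = 0.259 with an estimated correlation). Examples were miR-880 at 33586 ± 17816 CPM in Thy1+ against 4253 ± 47.6 in Thy1- (log2 2.48, SE 0.60), miR-881 at 2.22 and miR-741 at 2.11. In the Sfmbt2 cluster, a large set of related miRNAs mostly within 1 gene, 19 of 33 rose (15 of 29 with names of equal counts taken once) and 0 fell, or 26 and 0 when adjusted over the list alone (camera adjusted p = 2.77e-07; adjusted p = 0.259 with an estimated correlation), among them miR-297a at 2.13 and miR-297c at 1.99.

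Of 15 let-7 products, 10 fell and 0 rose, or 13 and 0 when adjusted over the list alone (camera adjusted p = 3.00e-06; adjusted p = 0.259 with an estimated correlation). let-7f was at 42957 ± 59.3 CPM in Thy1+ and 100509 ± 31214 in Thy1- (log2 -1.75, SE 0.49), and let-7b fell by 1.83 on the log2 scale. Under total scaling 2 let-7 products remained past the test, both lower in Thy1+, and with replicate number as a block 0 did (median -1.76). Both products of miR-202, a miRNA known from gonads, fell, miR-202-5p from 10202 ± 9846 CPM in Thy1- to 1425 ± 770.4 in Thy1+ (log2 -3.35, SE 0.78) and miR-202-3p by 2.42 on the log2 scale. The miR-202 hairpin lies on chromosome 7 at 139957689 to 139957760. Other large falls were those of miR-196a (log2 -2.57), miR-365 (-2.45), miR-503 (-2.37) and miR-322 (-2.29).

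All 9 products of the blood list passed the test, but in both directions. The list as a whole did not pass camera (adjusted p = 0.108) but passed fry as higher (adjusted p = 0.0374). Adjustment over the list alone gave the same 6 higher and 3 lower. The 6 products of miR-142, miR-150, miR-155 and miR-223, known from white blood cells, rose, with miR-142-3p at 19794 ± 7745 CPM in Thy1+ against 1624 ± 467 in Thy1- (log2 3.04, SE 0.50) and miR-223 at 239 ± 98.6 against 7.73 ± 2.61 CPM (log2 4.30). The 3 known from red blood cells, miR-144, miR-451 and miR-486, fell (log2 -4.25, -3.47 and -2.42). White cell miRNAs were thus higher in the same libraries in which the miR-183, pluripotency and X-linked clusters were higher. Of the miR-17 clusters, 4 of 19 rose and 2 fell, over all miRNAs and over the list alone (camera adjusted p = 0.852), with a median of -0.07, a mean of 0.34 and a test that leaned higher. miR-20b (log2 3.22), miR-363 (3.14), miR-18b (2.72) and miR-106a (2.11), which rose, lie in the cluster on the X chromosome, and miR-17* (-1.91) and miR-106b (-1.44) fell. Of 7 miR-200 family products, miR-200c (4.05) and miR-141 (2.10) rose (camera adjusted p = 0.852). In the muscle list miR-206 rose (2.84) and miR-1 did not pass (0.58). No product of the mesenchymal list passed (0 of 19), although the list leaned lower (camera adjusted p = 3.31e-03; adjusted p = 0.422 with an estimated correlation). Under RLE scaling 2 of these 19 fell. No product passed in the miR-34 family (0 of 6, camera adjusted p = 0.900), the Dlk1-Dio3 cluster (0 of 49, camera adjusted p = 0.181), the other tissues (0 of 3, camera adjusted p = 0.852), the miR-221 pair (0 of 2) or the endothelial miR-126 (0 of 2). The counts for the mesenchymal, muscle, endothelial, miR-200, miR-34, miR-221, miR-202, Dlk1-Dio3 and other tissue lists were equal when adjusted over the list alone. The Dlk1-Dio3 median was -0.25 and turned to 0.34 under total scaling. Under that scaling no miR-17 product fell (0 of 19), 1 miR-202 product did, and 1 of the miR-221 pair rose. The miR-17 median then turned to 0.51.

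By fry, the miR-183, let-7, X-linked, Sfmbt2 and blood lists passed (adjusted p = 0.0374 each). The study list (0.0717), the pluripotency clusters (0.0928) and the mesenchymal list (0.0972) passed the preset camera test but not fry. The edgeR test called 119 miRNAs, with a biological coefficient of variation of 42.8%. Under total scaling 110 rose and 11 fell, and with replicate number as a block 28 rose and 4 fell. Under the block no product of let-7, the X-linked cluster, miR-202 or the muscle list passed, and 1 Sfmbt2 product rose. The 4 miR-183 cluster products still rose, with 8 of the pluripotency clusters, 4 of the study list, 3 of the miR-17 clusters and 1 of the miR-200 family, and in the blood list 4 rose and 2 fell. The edgeR calls were not kept when either Thy1+ library was left out, which left 1 library in that group, and the cause was not tested. On all 4 libraries DESeq2 called 148 and limma-voom 121.

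The next comparison set the culture, at about 10 passages, against the fresh Thy1+ fraction. The culture and the fresh fractions may hold different kinds of cells. Whether a difference arose in the germ cells themselves was not tested. Of 470 miRNAs, 42 were higher and 63 lower in the culture. Most miRNAs of the Dlk1-Dio3 cluster, an imprinted region on chromosome 12, were lower, as were miRNAs of white blood cells and several of the pluripotency clusters. miR-21, the miR-221 pair, known for promoting proliferation, and 8 of 15 let-7 products (1 under total scaling) were higher. miR-21 reached 118930 CPM in the culture against 30144 ± 3666 CPM in Thy1+ (log2 3.64, SE 0.52, adjusted p = 0.0104), and miR-379 of the Dlk1-Dio3 cluster was at 363 CPM against 17665 ± 7368 CPM (log2 -3.92, SE 0.71).

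Of 58 Dlk1-Dio3 products, 40 fell and 0 rose, or 50 and 0 when adjusted over the list alone (camera adjusted p = 2.15e-22; adjusted p = 0.296 with an estimated correlation). The cluster spans 109563692 to 109743795 on chromosome 12 in GRCm38. Its products held 3.21% (3.18% to 3.25%) and 6.15% (6.10% to 6.20%) of the counts of the Thy1+ libraries, 3.27% (3.25% to 3.29%) and 3.79% (3.77% to 3.81%) of those of the Thy1- libraries and 0.102% of the culture counts (0.0989% to 0.104%), again with 95% intervals. The median log2 fold change was -4.10 and all 58 values were below 0. The culture had no count for 12 of them, and with these at their bound the median was -3.41. Of the 31 with more than 3 culture counts, 28 fell, with a median of -3.92. miR-434-3p (log2 -5.33), miR-134 (-4.28), miR-541 (-3.39) and miR-127 (-4.54), which lies opposite an exon of Rtl1, were among those that fell.

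**Figure D2:**
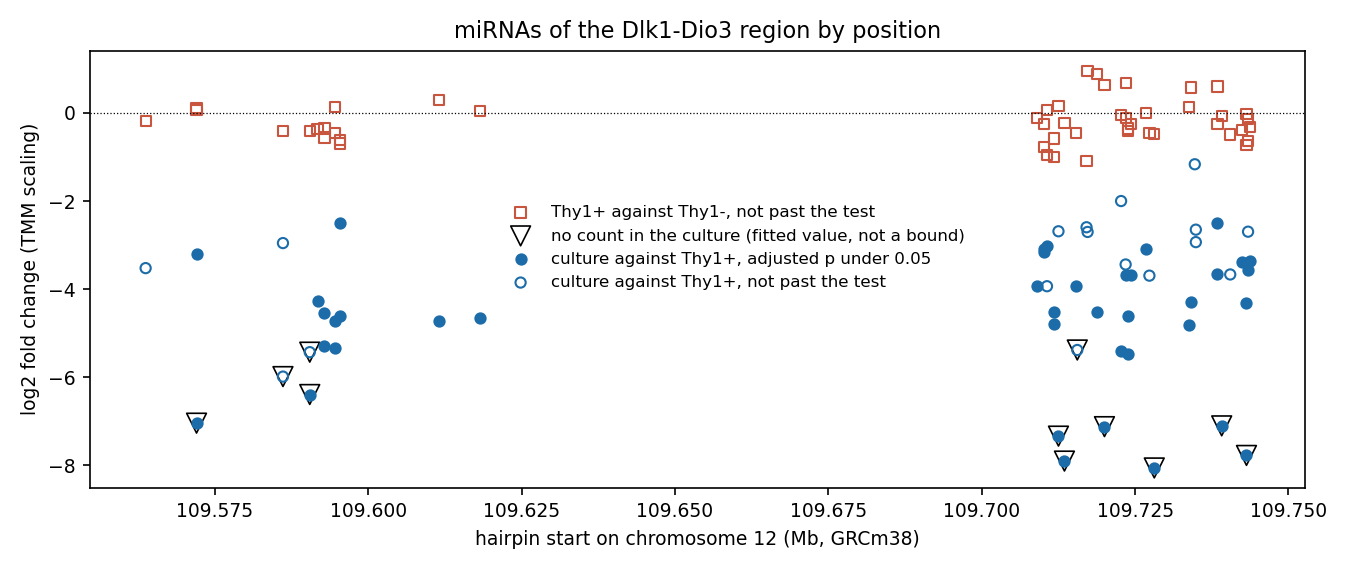
Log2 fold change (TMM scaling) of miRNAs of the Dlk1-Dio3 region against the start of their hairpin on chromosome 12 (Mb, GRCm38). Circles are culture against Thy1+ (filled where the adjusted p is under 0.05), squares are Thy1+ against Thy1-, and triangles mark miRNAs with no culture count, whose fitted values are not bounds. The circles lie below 0 across the region and the squares lie around 0.

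Of 15 let-7 products, 8 rose and 0 fell, over all miRNAs and over the list alone (camera adjusted p = 2.62e-06; adjusted p = 0.296 with an estimated correlation), led by let-7f (log2 3.17) with let-7a at 2.54. Under total scaling 1 remained past the test. By CPM, let-7f and let-7a were higher in the culture, while let-7c and let-7b were lower. let-7c was at 70086 CPM in the culture against 81790 and 92866 in the Thy1+ libraries, and let-7b at 12355 against 20170 and 17494. Both miR-221 and miR-222 rose (log2 4.05 and 4.35), from 351 ± 123 and 65.9 ± 20 CPM in Thy1+ to 1803 and 435 CPM. In the mesenchymal list 8 of 19 rose and 0 fell, or 9 and 0 when adjusted over the list alone (camera adjusted p = 2.85e-05; adjusted p = 0.310 with an estimated correlation), among them miR-143 (log2 2.72) and miR-199a-3p (2.66). With total scaling its median was 0.16, with 1 product higher and 1 lower. Other large rises were those of miR-217 (5.40), from 8.49 ± 0.0681 to 115 CPM, miR-216a (4.90), miR-146b (4.18), miR-125b-3p, from 62.6 ± 8.5 to 316 CPM, miR-206 (3.76), miR-335-5p (3.75) and miR-31 (3.52).

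Of the study list 3 of 8 products rose, or 4 when adjusted over the list alone (camera adjusted p = 0.0160; adjusted p = 0.296 with an estimated correlation), and again this list is not independent evidence. miR-21, miR-21* and miR-34c* rose. miR-34c, at 195531 CPM in the culture (log2 3.17), narrowly missed the test (adjusted p = 0.0541). Its family had 1 of 6 products higher, or 3 when adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.528 with an estimated correlation). miR-182 (log2 0.63), miR-183 (0.38), miR-146a (0.29) and miR-96 (0.21) did not pass, and under total scaling all 4 values were negative. None of the 4 miR-183 cluster products passed (camera adjusted p = 0.853), and neither did the 29 X-linked products (camera adjusted p = 0.135) or the 36 Sfmbt2 products (camera adjusted p = 0.231), with either adjustment. The miR-183 cluster had a mean of -0.10. The medians of these 3 lists, 0.30, 0.39 and 0.25, became -1.35, -1.28 and -1.40 under total scaling, and that of the study list went from 1.35 to -0.31.

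Of 9 blood products 5 fell and 0 rose, or 8 and 0 when adjusted over the list alone (camera adjusted p = 2.88e-03; adjusted p = 0.296 with an estimated correlation). miR-223 fell from 239 ± 98.6 to 0.783 CPM, which is 4 culture counts, and miR-142-3p from 19794 ± 7745 to 818 CPM (log2 -2.91, SE 0.68). miR-155 did not pass (log2 1.05). In the pluripotency clusters 4 of 12 fell and 0 rose, or 8 and 0 when adjusted over the list alone (camera adjusted p = 4.00e-03; adjusted p = 0.502 with an estimated correlation), among them miR-293 (log2 -2.61) and miR-291a-3p (-2.33). Under RLE scaling 2 of these 12 fell. In the miR-17 clusters miR-18b (-3.85), miR-363 (-3.01) and miR-20b (-2.67) of 20 products fell, or 2 when adjusted over the list alone (camera adjusted p = 3.38e-03; adjusted p = 0.296 with an estimated correlation). In the miR-200 family miR-429 (-3.51), miR-200b (-3.19) and miR-200a (-3.17) of 8 fell, or 4 when adjusted over the list alone (camera adjusted p = 0.0160; adjusted p = 0.296 with an estimated correlation). miR-206 was the only one of 3 muscle products called (camera adjusted p = 0.853), and adjusted over the list alone 1 was higher and 1 lower. miR-122 (log2 2.51) was the only one of 7 in the other tissues, or 2 when adjusted over the list alone (camera adjusted p = 0.853) with a list median of -0.99 and a test that leaned higher. The muscle list had a median of -2.19, or -0.13 with the 1 product lacking culture counts at its bound, and a test that leaned higher. Neither miR-202 product nor either miR-126 product passed, with either adjustment. Total scaling moved many of these counts. Under it 18 of 20 miR-17 products, 9 of 12 pluripotency products, 8 of 9 blood products and 7 of 8 miR-200 products fell, as did 54 of 58 in the Dlk1-Dio3 cluster. The X-linked cluster then had 2 lower, the Sfmbt2 cluster 4, miR-202 2, the miR-183 cluster 1, the muscle list 1 and the other tissues 2, each with 0 higher. The miR-34 family had 0 past the test and the study list 1 higher and 1 lower.

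By fry, let-7 and the miR-17 clusters (adjusted p = 0.0485 each) and the blood list (0.0308) passed. The Dlk1-Dio3 cluster (0.0918), the miR-200 family (0.0918) and the mesenchymal list (0.0844) passed the preset camera test but not fry. The same held for the study list (0.162), the pluripotency clusters (0.232) and the miR-34 family (0.345). With edgeR 105 miRNAs were called. Under total scaling 9 rose and 168 fell, among them all 63 lower under TMM scaling. Without Thy1+ replicate 1 or replicate 2 edgeR called 0 miRNAs (142 and 117 at an unadjusted p under 0.05); on all 5 libraries DESeq2 called 121 and limma-voom 92.

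The last comparison set the culture against the fresh Thy1- fraction. Of 470 miRNAs, 85 were higher and 79 lower in the culture. All products of the study list and of the miR-183 cluster were higher, with 17 of 29 in the X-linked cluster and miR-221 and miR-222. In the Dlk1-Dio3 cluster 48 of 58 products were lower, as were both miR-202 products and the 3 red blood cell miRNAs. miR-146a stood at 1962 CPM against 153 ± 120.5 in Thy1- (log2 4.81, SE 0.73), miR-21 at 118930 against 11617 ± 129.8 CPM (log2 4.40, SE 0.53, adjusted p = 2.24e-03) and miR-34c at 195531 against 28646 ± 28493 CPM (log2 3.92, SE 1.04, adjusted p = 0.0212).

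Of the study list 8 of 8 rose, also when adjusted over the list alone (camera adjusted p = 3.26e-06; adjusted p = 0.251 with an estimated correlation), with the same reservation on its choice. The 4 miR-183 cluster products rose, also when adjusted over the list alone (camera adjusted p = 9.83e-04; adjusted p = 0.300 with an estimated correlation), with miR-182 at log2 4.20 and miR-183 at 3.66. In the X-linked cluster 17 of 29 rose (15 of 27 with names of equal counts taken once) and 0 fell, or 20 and 0 when adjusted over the list alone (camera adjusted p = 7.13e-07; adjusted p = 0.251 with an estimated correlation), among them miR-741 (3.08) and miR-881 (2.63). Under total scaling 5 of them rose and 1 fell. In the Sfmbt2 cluster 19 of 36 rose (15 of 32 with names of equal counts taken once) and 0 fell, or 22 and 0 when adjusted over the list alone (camera adjusted p = 7.13e-07; adjusted p = 0.300 with an estimated correlation), among them miR-467a (2.55) and miR-467e (2.09), and under total scaling 2 did. In the miR-34 family miR-34c, miR-34c* and miR-34b-3p of 6 rose, or 4 when adjusted over the list alone (camera adjusted p = 0.0729). miR-222 (log2 5.57) and miR-221 (4.73) rose, as did miR-206 (6.55), miR-217 (6.32), miR-216a (5.92), miR-146b (5.53), miR-29a (4.88) and miR-31 (4.52).

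Of 58 Dlk1-Dio3 products 48 fell and 0 rose, or 49 and 0 when adjusted over the list alone (camera adjusted p = 1.14e-20; adjusted p = 0.300 with an estimated correlation). Their median was -4.20, or -3.76 over 57 products with those lacking culture counts at their bound, and 29 of the 31 with more than 3 culture counts fell. miR-434-3p fell by 5.24 and miR-379 by 4.08 on the log2 scale. miR-451 and miR-144 fell too (log2 -6.88 and -6.41), with 3.91 and 0.978 CPM left in the culture, as did miR-486 (-4.18). In the blood list 3 of 9 thus fell and miR-155 rose (4.55), with either adjustment (camera adjusted p = 0.185). miR-142-3p did not pass (log2 0.08, -0.99 under total scaling). Both miR-202 products fell (log2 -5.03 and -3.78), and miR-672 fell from 2267 ± 243 to 27.6 CPM (log2 -5.33). In the miR-200 family miR-429 (-5.01), miR-200a (-4.90) and miR-200b (-3.07) of 8 fell, or 5 with 1 higher when adjusted over the list alone (camera adjusted p = 0.171). In the miR-17 clusters miR-17* (-3.07), miR-18a (-2.64) and miR-106b (-2.62) of 20 fell, or 2 when adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.375 with an estimated correlation). In the mesenchymal list miR-125b-3p, miR-143, miR-199a-3p and miR-199b of 19 rose, or 1 when adjusted over the list alone (camera adjusted p = 0.187). In the pluripotency clusters miR-292-5p (2.11) of 12 rose, or 0 when adjusted over the list alone (camera adjusted p = 0.158). No let-7 product of 15 passed, with either adjustment (camera adjusted p = 0.614), and the median of 0.52 became -0.55 under total scaling. let-7c-1*, which is outside the list, fell (-2.83). miR-206 of 3 muscle products rose (camera adjusted p = 0.586) with a list median of -1.66, or -1.56 with the product lacking culture counts at its bound. miR-122 of 7 in the other tissues rose (camera adjusted p = 0.558), and that list's median of -0.36 became 0.23 over the 6 products with a culture count. The counts of the muscle, other tissue, miR-221 and miR-202 lists were equal when adjusted over the list alone, and neither miR-126 product passed. Under total scaling 5 products of the study list, 3 of the miR-183 cluster and 1 of the miR-34 family rose, and 0 of the pluripotency clusters. The mesenchymal list then had 1 higher and 2 lower, with a median of 0.03. The miR-17 clusters had 9 lower, the miR-200 family 5, let-7 2, the blood list 4 and the muscle list 1.

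**Figure D3:**
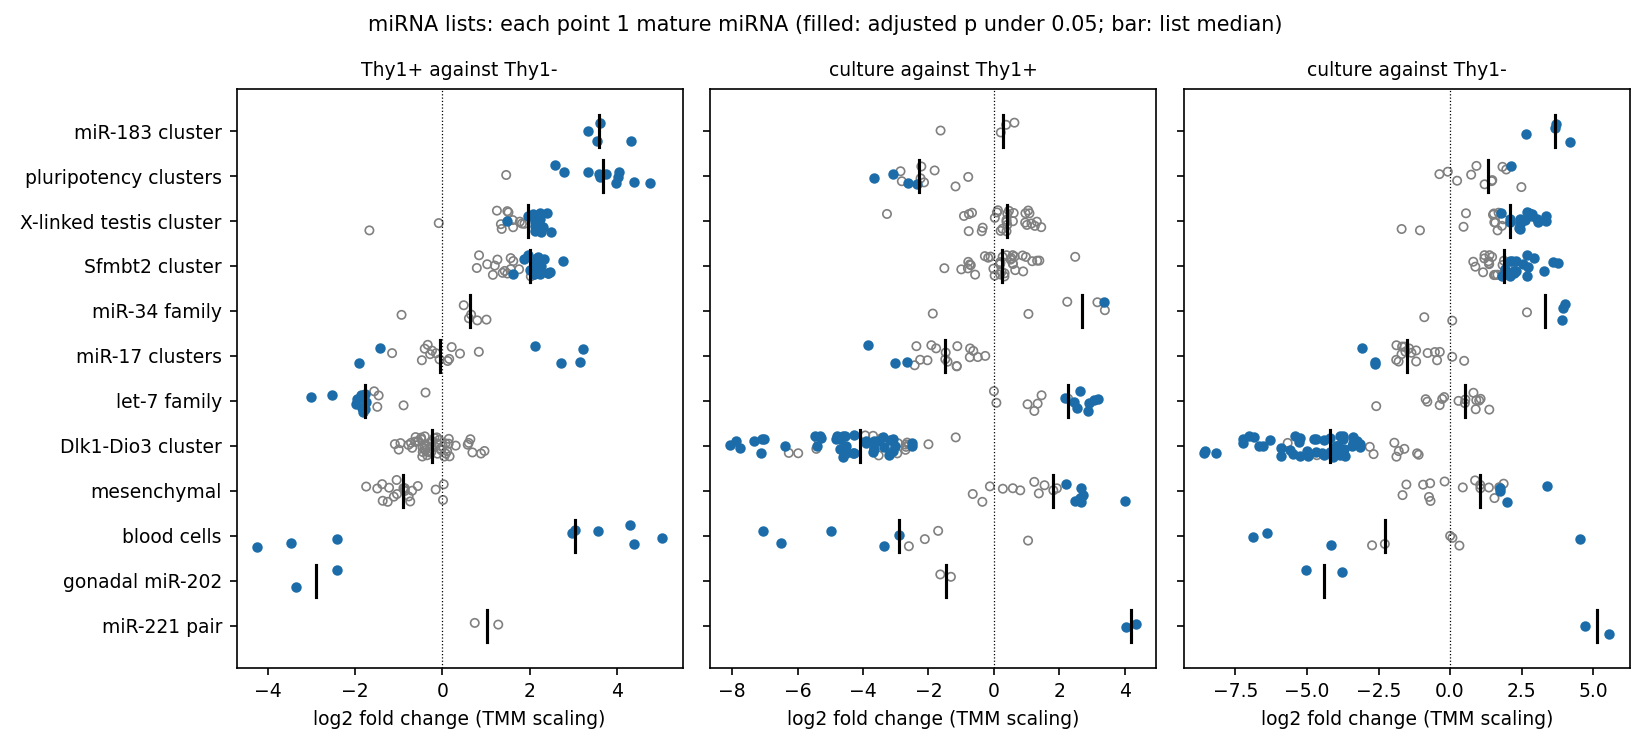
Log2 fold change (TMM scaling, horizontal axis) of the tested members of 12 miRNA lists in the 3 comparisons. Each point is a mature miRNA, filled where the adjusted p is under 0.05, and each bar is the list median. The Dlk1-Dio3 medians lie at -4.10 and -4.20 for the culture against Thy1+ and Thy1-, and at -0.25 for Thy1+ against Thy1-, where total scaling turned it to 0.34. Total scaling also turned the sign of the small positive medians of the miR-183, X-linked and Sfmbt2 lists in culture against Thy1+ and of let-7 in culture against Thy1-. The miR-17 median in Thy1+ against Thy1- turned from -0.07 to 0.51.

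By fry, the study, miR-183, X-linked and Sfmbt2 lists passed as higher and the miR-17 and blood lists as lower (adjusted p = 0.0300 each). The Dlk1-Dio3 cluster passed the preset camera test but not fry (adjusted p = 0.0727). With edgeR 164 miRNAs were called, and under total scaling 34 rose and 123 fell. A fit of the culture and Thy1- libraries alone called 0 (171 at an unadjusted p under 0.05), and leaving out Thy1+ replicate 1, Thy1+ replicate 2 or Thy1- replicate 1 left 81, 41 and 90; on all 5 libraries DESeq2 called 166 and limma-voom 150.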

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

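All tests on the causes of these results were chosen after the results were seen. The reads in the files also hold base changes against the mature sequences, which the comparisons of levels did not use. Changes of A to G were compared site by site between the culture and the fresh libraries, and no other base change was. C-to-T changes made up 0.669% of C bases in Thy1+ replicate 2 and 0.610% in Thy1- replicate 2, against 0.145% and 0.175% in the libraries numbered 1 and 0.133% in the culture. Their 95% Clopper-Pearson intervals ran from 0.658% to 0.679% and from 0.606% to 0.615% in the libraries numbered 2, and from 0.130% to 0.179% over the others.

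The C-to-T excess was 4.60-fold in Thy1+ and 3.49-fold in Thy1-. The C-to-T share was higher in replicate 2, by any amount, at 89.3% and 88.2% of 262 C positions. That is beyond an even split between the replicates, which argues against strain variants or RNA editing at a few sites. A-to-C changes moved the other way, to 0.297 and 0.271 times the level of replicate 1, so a sequencing or library batch that goes with the replicate number may account for both, although they came apart in the culture, where A-to-C was at 0.0441%, near the 0.0362% and 0.0410% of number 2, and C-to-T near number 1. Differences in miRNA levels between the replicates were not shared between the fractions across 425 miRNAs (Pearson r -0.0603, with 2 pairs of libraries), which argues against a common shift of levels with the number, but not against one in a few, since miR-34c, miR-34b-5p, miR-34b-3p and miR-449a were more than 2-fold higher in number 1 in both fractions (of 21 miRNAs over 2-fold in both, 7 went the same way and 14 did not). The labels name no batch, and no other biological explanation was tested.

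In miR-411, A5G, counted from 1 at the 5′ end of the mature miRNA, was in 10.6% of 151 culture reads (95% Clopper-Pearson interval 6.18% to 16.6%), against 2.37% and 2.47% in the Thy1+ libraries and 2.22% and 1.66% in the Thy1- libraries (intervals from 1.27% to 4.02%). Fisher's exact adjusted p over 858 sites was 1.55e-05. The test pools the reads of the 4 fresh libraries against 1 culture library, so it ignores the spread between samples. It was passed by 5 sites, all higher in the culture. The others were miR-378 A16G at 0.802% in the culture (0.689% to 0.927%), against 0.186% and 0.299% in the Thy1+ libraries and 0.288% and 0.152% in the Thy1- libraries, miR-151-3p A3G at 0.507%, miR-378 A6G at 0.403% and miR-378 A12G at 0.186%. In miR-411 A5G and miR-378 A16G the culture interval lay above those of all 4 fresh libraries.

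White blood cell miRNAs were higher in Thy1+, and expression in the germ cells themselves stays open, as it was not tested. The beads bind Thy1, which T cells also carry, so the selection would not remove them, and miR-142-3p was at 19794 CPM in Thy1+ beside miR-223 at 239 and miR-150 at 60.5. Which kind of white cell, if any, carried these miRNAs was not tested. Whole blood carried unsorted into the Thy1+ fraction is argued against by the 3 red cell miRNAs, which were lower in Thy1+ (median log2 -3.47). They cannot decide on white cells of the blood that the beads retained apart from red cells. Scaling is argued against by the lowest value over 6 products and 4 scalings, 2.93. Leukocytes in the Thy1+ fraction that the culture no longer holds could explain part of the pattern, since the median of the 6 products was -3.95 in culture against Thy1+, or -2.75 with the product lacking culture counts at its bound. Of the 6 products 4 fell and miR-142-5p (-2.60) just missed the test, while miR-155 did not pass (1.05, or -0.61 under total scaling), and miR-142-3p kept 818 CPM in the culture and did not differ past the test from Thy1- (log2 0.08).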

How the results depend on the processing

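All alternatives were planned except the crossed block and taking names of equal counts once. No named miRNA, and no list test under the alternatives it was rerun with, turned its direction where it or the alternative was past the test. The study list median in culture against Thy1+ went from 1.35 to -0.31 under total scaling. For Thy1+ against Thy1- (119 called), a filter at 100 CPM gave 79 of 236 tested, where fewer miRNAs were tested, and the replicate block gave 32. The crossed block, with the same number of terms, gave 163. The 33 lower became 11 under total scaling, 59 without a filter, 62 with DESeq2, 19 with tags of 20 to 24 bases and 65 at an adjusted p of 0.10. Leaving out 1 library gave 0 to 137, with 0 without either Thy1+ library. For culture against Thy1+ (105 called), total scaling gave 177, an adjusted p of 0.10 gave 163, no filter moved the 42 higher to 64, the 100 CPM filter moved the 63 lower to 41, and leaving out 1 library gave 0 to 120, with 0 without either Thy1+ library. For culture against Thy1- (164 called), the 100 CPM filter gave 101 of 245 tested, leaving out 1 library gave 41 to 128, and the culture and Thy1- libraries alone gave 0. Its near-even split of 85 higher and 79 lower turned to mostly lower under total scaling (34 and 123) and without Thy1- replicate 1 (33 and 57), and less so without Thy1+ replicate 2 (17 and 24). It stayed near-even under the other alternatives that called any miRNA, such as DESeq2 (82 and 84) and the 100 CPM filter (47 and 54). The cause of the changes with scaling, with the block and of the losses beyond the smaller number of libraries was not tested. The other alternatives stayed within 1.5 times each total number called. Because some fits called nothing, 0 of the 35, 35 and 46 named miRNAs called in the 3 comparisons passed under every alternative, and 0 reversed. Lists were rerun with the preset camera test only, and not under every alternative. The alternatives used were RLE and total scaling, tags with a single name and each left-out fresh library. The block was added for Thy1+ against Thy1-. Of these list values, 101 of 104, 96 of 97 and 93 of 97 kept their side of the threshold. Under camera with an estimated correlation no list passed, and the smallest adjusted p of the 3 comparisons was 0.259, 0.296 and 0.251. With names of equal counts taken once, the higher calls of the 3 comparisons went from 86 to 80, from 42 to 41 and from 85 to 78, those of the mesenchymal list in the culture from 8 to 7 and from 4 to 3, and the lower calls stayed. The culture had no count for 12 of 58 Dlk1-Dio3 products and 1 of 3 muscle products.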

Other observations

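The tests and miRNAs in this part were chosen after their values were seen. Some neighbours on the X chromosome moved apart in the fresh fractions. This was seen in picked miRNAs, and neither cluster was tested as a set. miR-322 (log2 -2.29), miR-503 (-2.37), miR-351 (-1.96) and miR-542-3p (-1.66) were lower in Thy1+ than in Thy1-, with miR-322 at 2931 ± 482 against 9687 ± 2187 CPM (SD, n = 2), while miR-20b (3.22) of the X-linked miR-106a cluster was at 913 ± 69.6 against 65.6 ± 20.1 CPM. miR-351 and miR-542-3p did not pass under total scaling (-1.39 and -1.13). miR-29a was higher in Thy1+ (log2 2.74, 4763 ± 1077 against 504 ± 168 CPM), as were miR-29a* (3.37) and miR-29b* (2.98), while miR-29b (2.05) narrowly missed the test and miR-29c did not pass it (-0.59).

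In the culture, miR-23a (log2 3.16), miR-24 (2.14) and miR-24-2* (2.33) were higher than in Thy1+, and miR-27a (1.85) just missed the test. Under total scaling these values were 1.51, 0.53, 0.67 and 0.19, none past the test. miR-672 was lower in the culture than in Thy1+ (log2 -3.82), at 27.6 CPM against 1227 ± 82.5.

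Most Dlk1-Dio3 miRNAs were lower in the culture. Scaling of the culture library is argued against by the list's median closest to 0 over 4 scalings, -4.01. The mesenchymal list was not lower in the culture, with a lowest median over the scalings of 0.16. This cannot decide whether the mesenchymal cells of the fresh fraction were lost, since mesenchymal cells in the culture itself could hold the list up. Loss of somatic cells depleted by the Thy1 selection is argued against by the near-equal Dlk1-Dio3 levels in the fresh fractions (median -0.25). A change in this culture alone and an effect of culture in general cannot be told apart, since there was 1 culture library. Loss of another cell type that carries these miRNAs could also remain, and was not tested.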
